A study of Mus musculus with 18 samples.

How the data were processed

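Poly-A RNA from 18 mouse livers was sequenced as single reads of 50 nt, 1 library per mouse, in 6 groups of 3. Per the submitters' processing notes, reads were trimmed with Trim Galore and aligned with TopHat2 to mm10, with no versions given. Read counts per gene were made before they were deposited with featureCounts 1.5.0-p1 on exons of Ensembl 82 genes (GRCm38), per the file headers. They used a minimum overlap of 10 bases, no strand, and a read was counted for each gene it overlapped, while reads aligned to several places were not counted. The values are raw counts for 34937 genes.

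Gene IDs were matched to symbols in a reference table of gene names, which named 34599 of them. The libraries held 23.1 to 75.3 M counts and 19763 to 22315 genes with at least 1 count. A check for duplicated libraries gave a chi-square per gene of 33.9 to 310 between replicates, where copies or splits of 1 library would give about 1 or less. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr at a minimum count of 10, which left 17789 genes, 17692 of them with a symbol. All 18 libraries entered a single quasi-likelihood fit after TMM scaling, with 12 residual degrees of freedom and a biological coefficient of variation of 0.202. Each comparison was a two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment over all genes at 0.05. Standard errors are the log2 fold change divided by the root of F, and CPM values are normalised, with SD over 3 mice.

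The design text gave 5 comparisons, 12ON with 12 and each OFF group with 12ON. The OFF groups were also compared with group 12, and 7OFF with 1OFF, which makes 10. Groups, comparisons, 40 gene lists, the rule for naming genes and the alternatives below were, but for those on Xist and the mitochondrial share, set before the data were examined. The lists held 817 distinct genes, of which 794 were tested. Their medians, counts of passing members and tests are given with the results. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry.

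Genes were named by a rule. Myc and Esr1, the parts of the construct, were named in each main comparison. The 12 highest and 12 lowest log2 fold changes in 12ON vs 12, and 6 and 6 in each OFF group against 12ON, were named among genes with an adjusted p under 0.05, a mean of at least 4 CPM and no overlap between groups. This left 5777, 0, 0, 4274 and 5395 genes to choose from. For each list up to 4 members in each direction with the smallest p could be named, or, where none passed, the 2 with the smallest p as values. Some genes that the rule names are not reported here.

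Genes changed in 12ON vs 12 were followed in the OFF groups, with 10 simulated runs per group in which an OFF group equalled 12ON or group 12. The fit was tested on simulated data drawn from the means and library sizes of the real genes. For 12ON vs 12 on 17633 genes, 20%, 50%, 84% and 92% of 50 genes changed 1.5, 2, 4 and 8-fold were recovered, with 3 false calls. For 1OFF vs 12ON on 17625 genes the shares were 30%, 66%, 92% and 88%, with 5 false calls.

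The alternatives were other scalings, filters and thresholds, DESeq2 1.42.0, fits of 2 groups alone, a replicate block, a test against a 1.5-fold change, and leaving out each library in turn. A term for high or low Xist, a term for the mitochondrial share, and the libraries with low Xist alone, were added after the data had been seen. No library was left out of the results unless stated.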

Results

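RNA from the livers of 18 mice was sequenced as poly-A libraries, in 6 groups of 3 mice. The mice had been injured with carbon tetrachloride, a hepatotoxin that damages hepatocytes around the central vein, given intraperitoneally at 0.5 µL per g of body weight. MycER is a fusion of the transcription factor MYC to a hormone-binding domain of the estrogen receptor, and daily intraperitoneal tamoxifen at 1 mg activated it. Groups 12 and 12ON were sampled 12 days after injury, without and with MycER activation. The labels give groups 1OFF, 2OFF, 3OFF and 7OFF as 1, 2, 3 and 7 days after injury without activation, and do not state whether MycER had been active in these mice earlier. They also do not give the sex of the mice, the hour of sampling or whether group 12 received tamoxifen.

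The libraries held 23.1 to 75.3 M gene counts, with 19763 to 22315 genes detected in each. In the 12ON libraries Alb, which encodes albumin, took 2.86% ± 0.28 of the counts (SD, n = 3), against 7.79% ± 0.73 in group 12. H19, a long non-coding RNA of the fetal liver, took 2.42% ± 0.35 in 12ON and 0.00803% ± 0.00513 in group 12. Xist, expressed from the inactive X chromosome of females, lay between 276 and 455 CPM in 1 library each of groups 12, 12ON, 2OFF, 3OFF and 7OFF, and between 0.21 and 1.94 CPM in all other libraries. Group 1OFF held no library with high Xist. The mitochondrial chromosome gave 4.80% to 5.25% of the counts in group 12, 6.42% to 7.11% in 12ON, 6.16% to 7.33% in 1OFF, 6.69% to 7.00% in 2OFF, 5.36% to 7.18% in 3OFF and 5.54% to 6.19% in 7OFF. Errors of log2 fold changes below are standard errors, with n = 3 mice per group, and calls rest on edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Where leaving out 1 library moved the fold of a called gene or the median of a list called by camera by over 1.5 times, or ended the call, the values without it are given. An adjusted p of camera beside such a median, with the preset correlation, marks a call that ended.

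The first comparison asked how 12ON livers differed from those of group 12. Most tested genes of ribosome biogenesis and mitosis were higher, and most of secreted hepatocyte proteins, the acute phase and cholesterol synthesis lower. As lists they had an adjusted p = 0.21 or more with an estimated correlation. H19 (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143 in GRCm38) rose 217-fold, from 93.1 ± 54.1 to 20260 ± 2810 CPM (SD). The fetal growth factor gene Igf2 rose 186-fold, from 25.7 ± 12.7 to 4781 ± 984 CPM, and Dlk1, a marker of hepatoblasts, 208-fold, from 0.22 ± 0.15 to 53.1 ± 23.1 CPM. Of 17789 genes tested, 4269 were higher and 4029 lower in 12ON, of which 1761 and 1449 changed at least 2-fold. With a term for the mitochondrial share, which did not overlap between these groups, 2327 were higher and 1788 lower, and which part of the difference goes with that share stays open.

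**Figure D1:**
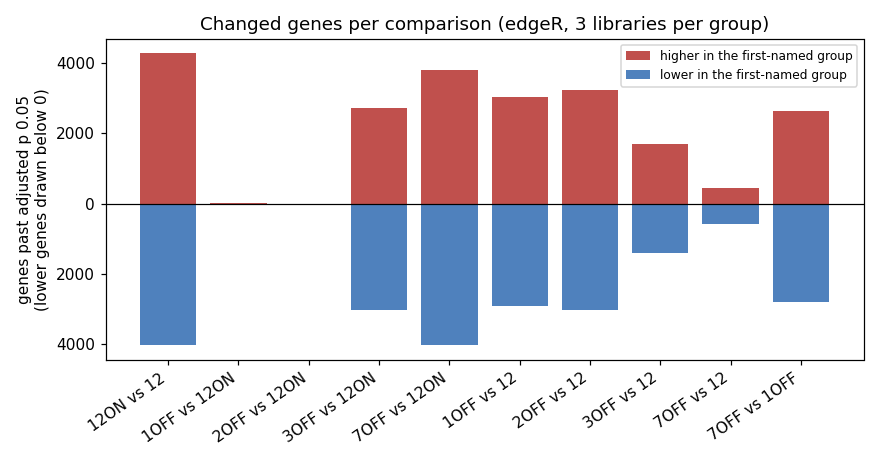
Number of genes past an adjusted p of 0.05 in each comparison, with genes higher in the first-named group drawn above 0 and lower genes below. The bars for 12ON vs 12 stand for 4269 and 4029 genes, and those for 1OFF vs 12ON and 2OFF vs 12ON for 1 and 0 genes.

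Myc (chromosome 15, 61985341 to 61990374) lay at 6.26 ± 0.98 CPM in 12ON and 7.37 ± 1.88 CPM in group 12 (SD), a log2 difference of -0.24 ± 0.25 that did not pass (adjusted p = 0.455). Esr1, the estrogen receptor gene whose hormone-binding domain the fusion carries (chromosome 10, 4611593 to 5005614), fell from 38.1 ± 4.08 to 10.1 ± 1.18 CPM (log2 -1.91 ± 0.34, adjusted p = 0.000276). Counts of a transgene read and of an endogenous read cannot be separated in these gene totals. Besides H19, Igf2 and Dlk1, genes with high log2 fold changes were Igf2os (8.30 ± 0.76), Mir675 (7.85 ± 0.81), Defb1 (7.57 ± 0.75), Gpx6 (7.35 ± 0.65), Cacna1b (6.92 ± 0.60), Amn (6.61 ± 0.46), Shisa8 (6.42 ± 0.57) and Timp4 (6.39 ± 0.98). Mir675 lies within H19 and Igf2os overlaps Igf2, and reads were counted for every overlapping gene without strand, so these cannot be told from their hosts. Group 12 means of Igf2os and Defb1 were 0.0573 and 0.0860 CPM, which leaves their folds uncertain. The lowest were Sfrp5 (-7.42 ± 1.23), A1bg (-7.20 ± 2.06), Krt79 (-6.92 ± 1.35) and Slc34a2 (-6.84 ± 1.32) and the major urinary protein genes Mup7 (-7.13 ± 1.46), Mup17 (-6.96 ± 1.38), Mup14 (-6.92 ± 1.32), Mup10 (-6.92 ± 1.28), Mup1 (-6.85 ± 1.31), Mup12 (-6.81 ± 1.29), Mup15 (-6.81 ± 1.32) and Mup8 (-6.81 ± 1.31). The Mup genes are near-identical copies, and reads aligned to several places were not counted, so their values rest on the reads that differ between copies and are uncertain. Igf2os (9.11 without 12 replicate 3), Mir675 (8.44 without 12 replicate 3), Defb1 (512-fold without 12 replicate 3), Gpx6 (8.26 without 12 replicate 3), Sfrp5 (-6.54 without 12 replicate 2, -8.13 without 12ON replicate 2), A1bg (-5.97 without 12 replicate 3, -8.45 without 12ON replicate 3), Krt79 (-5.83 without 12 replicate 3, -7.83 without 12ON replicate 1), Slc34a2 (-7.92 without 12ON replicate 1) and the 8 Mup genes (-6.31 to -6.06 without 12 replicate 1, -7.81 to -7.40 without 12ON replicate 1) moved by over 1.5 times in fold.

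Of the 44 canonical MYC target genes, 35 rose and 1 fell (35 and 2 adjusted over the list alone), with a median log2 fold change of 0.91 and an adjusted p = 0.21 with an estimated correlation. Among them were Ncl (2.04 ± 0.12), Fbl (1.61 ± 0.10), Npm1 (1.62 ± 0.11) and Nop56 (2.33 ± 0.19), which encode nucleolar proteins. Of the 42 genes of ribosome biogenesis, 39 rose and 1 fell (39 and 1 adjusted over the list alone), with a median log2 fold change of 0.84 and an adjusted p = 0.21 with an estimated correlation. Polr1a and Polr1b, subunits of RNA polymerase I, rose by log2 1.48 ± 0.11 and 1.87 ± 0.16. Of the 30 cytosolic ribosomal protein genes, 30 rose and 0 fell (30 and 0 adjusted over the list alone), with a median log2 fold change of 0.92 and an adjusted p = 0.323 with an estimated correlation. Examples were Rpl32 (1.35 ± 0.14), Rps19 (1.22 ± 0.13) and Rpl13 (1.23 ± 0.13). Of the 25 nucleotide synthesis genes, 18 rose and 1 fell (18 and 1 adjusted over the list alone), with a median log2 fold change of 0.84 and an adjusted p = 0.21 with an estimated correlation. They included the amidotransferase gene Ppat (1.91 ± 0.15) and the CTP synthase gene Ctps (2.60 ± 0.20). Of the 30 genes of G1/S and DNA replication, 25 rose and 1 fell (25 and 1 adjusted over the list alone), with a median log2 fold change of 1.85 and an adjusted p = 0.317 with an estimated correlation. The licensing factor Cdt1 (2.55 ± 0.26) and the helicase subunit Mcm6 (2.90 ± 0.35) rose, and Mcm10 fell (-1.41 ± 0.50). Of the 30 mitosis genes, 30 rose and 0 fell (30 and 0 adjusted over the list alone), with a median log2 fold change of 3.16 and an adjusted p = 0.323 with an estimated correlation. The kinase genes Cdk1 and Ttk rose by 3.39 ± 0.42 and 3.98 ± 0.52. Of the 24 p53 targets and CDK inhibitors, 12 rose and 4 fell (14 and 4 adjusted over the list alone), with a median log2 fold change of 0.74 and an adjusted p = 0.4 with an estimated correlation. Phlda3 (2.49 ± 0.34), Zmat3 (1.60 ± 0.21) and Bax (1.25 ± 0.20) rose, while Fas (-1.06 ± 0.15), Perp (-0.82 ± 0.11) and Gdf15 (-1.18 ± 0.37) fell. Mcm10 no longer passed without 12 replicate 2 or 3 or 12ON replicate 1 or 2 (adjusted p from 0.0661 to 0.103) and Gdf15 without 12 replicate 3 or 12ON replicate 2 (adjusted p from 0.0501 to 0.056).

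**Figure D2:**
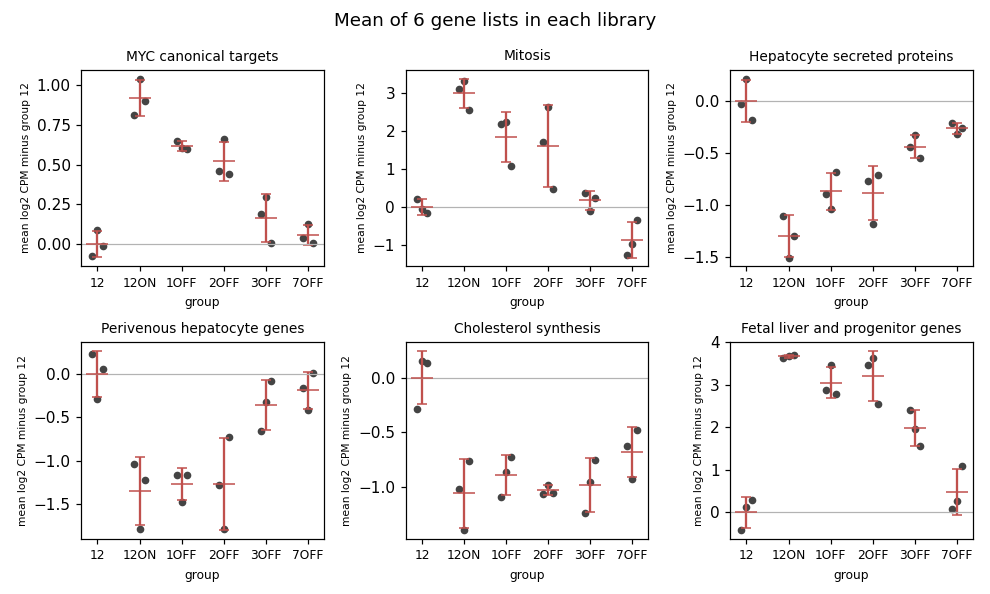
Mean log2 CPM of the members of 6 gene lists in each library minus the mean of group 12, by group, with points for the 3 mice and red bars for mean and SD. The mitosis list had a median log2 fold change of 3.16 in 12ON vs 12 and of -3.90 in 7OFF vs 12ON.

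Of the 25 genes of secreted hepatocyte proteins, 0 rose and 23 fell (0 and 24 adjusted over the list alone), with a median log2 fold change of -1.20 and an adjusted p = 0.21 with an estimated correlation. Examples were Alb (-1.93 ± 0.23), the transthyretin gene Ttr (-1.85 ± 0.22) and the apolipoprotein gene Apoc3 (-1.58 ± 0.14). With a term for the mitochondrial share 10 of these 25 genes fell and 0 rose, with a median of -0.84. Of the 20 perivenous hepatocyte genes, 1 rose and 17 fell (1 and 17 adjusted over the list alone), with a median log2 fold change of -1.44 and an adjusted p = 0.36 with an estimated correlation. Glutamine synthetase, Glul, fell by 1.43 ± 0.23 and the ammonium transporter gene Rhbg had -2.49 ± 0.42, while the glutathione transferase gene Gstm3 rose (3.82 ± 0.40). Of the 20 periportal hepatocyte genes, 5 rose and 11 fell (5 and 13 adjusted over the list alone), with a median log2 fold change of -0.87. Pigr and Sult5a1 fell (-2.18 ± 0.39 and -6.10 ± 0.76), and the urea cycle gene Cps1 rose (0.91 ± 0.19). Of the 20 genes of bile acid and sterol catabolism, 1 rose and 11 fell (1 and 11 adjusted over the list alone), with a median log2 fold change of -0.77 and an adjusted p = 0.4 with an estimated correlation. The uptake transporter genes Slco1a1 and Slco1b2 fell (-5.21 ± 0.79 and -1.30 ± 0.23). Of the 24 cholesterol synthesis genes, 0 rose and 21 fell (0 and 22 adjusted over the list alone), with a median log2 fold change of -1.05 and an adjusted p = 0.323 with an estimated correlation. Examples were Ebp (-1.77 ± 0.15), Tm7sf2 (-1.69 ± 0.19) and Sc5d (-1.90 ± 0.24). Of the 18 fatty acid synthesis genes, 1 rose and 6 fell (1 and 6 adjusted over the list alone), with a median log2 fold change of -0.52. The desaturase gene Fads1 fell (-1.90 ± 0.30) and Scd2 rose (2.46 ± 0.42). Of the 25 genes of fatty acid oxidation and PPARA targets, 1 rose and 10 fell (1 and 9 adjusted over the list alone), with a median log2 fold change of -0.40 and an adjusted p = 0.61 with an estimated correlation. Fabp1, a fatty acid binding protein gene, fell (-2.11 ± 0.35). Of the 25 genes of gluconeogenesis and amino acid catabolism, 3 rose and 16 fell (3 and 18 adjusted over the list alone), with a median log2 fold change of -0.95 and an adjusted p = 0.4 with an estimated correlation. The fructose bisphosphatase gene Fbp1 fell (-1.98 ± 0.28). Of the 18 glycolysis genes, 8 rose and 2 fell (8 and 2 adjusted over the list alone), with a median log2 fold change of 0.42. Pfkp and Eno1 rose (1.58 ± 0.21 and 1.23 ± 0.18). Of the 25 oxidative phosphorylation genes, 6 rose and 1 fell (5 and 1 adjusted over the list alone), with a median log2 fold change of 0.08. Genes of fatty acid oxidation and PPARA targets had a median of -0.29 without 12 replicate 3 (camera adjusted p = 0.145).

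Of the 24 acute phase genes, 0 rose and 19 fell (0 and 20 adjusted over the list alone), with a median log2 fold change of -2.02 and an adjusted p = 0.379 with an estimated correlation. The orosomucoid gene Orm2 fell (-3.55 ± 0.56), as did Saa4 (-2.66 ± 0.38) and Serpina3m (-2.94 ± 0.37). Of the 22 interferon response genes, 0 rose and 17 fell (0 and 17 adjusted over the list alone), with a median log2 fold change of -0.97 and an adjusted p = 0.36 with an estimated correlation. Gbp2 fell (-1.63 ± 0.25). Of the 20 unfolded protein response genes, 0 rose and 12 fell (0 and 14 adjusted over the list alone), with a median log2 fold change of -0.97 and an adjusted p = 0.4 with an estimated correlation. They included Xbp1 (-1.26 ± 0.20) and Dnajb9 (-1.71 ± 0.25). Of the 18 drug-metabolism genes responsive to CAR and PXR, 8 rose and 2 fell (8 and 2 adjusted over the list alone), with a median log2 fold change of 0.40 and an adjusted p = 0.4 with an estimated correlation. The glutathione transferase genes Gsta1 and Gsta2 rose (5.72 ± 0.56 and 5.21 ± 0.43), and Cyp2c29 fell (-1.44 ± 0.29). Of the 19 NRF2 targets, 5 rose and 2 fell (5 and 2 adjusted over the list alone), with a median log2 fold change of 0.24. Glutathione reductase, Gsr, rose (0.68 ± 0.14). Of the 20 immediate early genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone), with a median log2 fold change of 0.25. Jun and Atf3 rose (1.70 ± 0.27 and 2.35 ± 0.38). Of the 15 circadian clock genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone), with a median log2 fold change of -0.46. Clock and Nr1d1 fell (-0.94 ± 0.14 and -1.43 ± 0.38). Of the 18 sex-biased liver genes, 4 rose and 7 fell (4 and 8 adjusted over the list alone), with a median log2 fold change of -2.31. Of the 17 genes of growth signals and YAP targets, 2 rose and 4 fell (2 and 4 adjusted over the list alone), with a median log2 fold change of -0.29. The receptor genes Lifr and Egfr fell (-3.73 ± 0.30 and -2.96 ± 0.61), and Tgfa rose (0.96 ± 0.14). Orm2 (-4.19 without 12ON replicate 1) and Egfr (-3.69 without 12ON replicate 1) moved by over 1.5 times in fold. Unfolded protein response genes had a median of -0.28 without 12 replicate 2. Drug-metabolism genes responsive to CAR and PXR had a median of 0.61 without 12 replicate 1, 0.12 without 12 replicate 2 (camera adjusted p = 0.0535), 0.78 without 12 replicate 3 and 0.71 without 12ON replicate 3.

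Markers of other cell types did not move together. Of the 14 fetal liver and progenitor genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 fold change of 3.02 and an adjusted p = 0.21 with an estimated correlation. Besides H19, Igf2 and Dlk1, the RNA-binding protein gene Igf2bp3 rose (5.07 ± 0.55). Of the 15 cholangiocyte markers, 9 rose and 2 fell (10 and 2 adjusted over the list alone), with a median log2 fold change of 1.45 and an adjusted p = 0.379 with an estimated correlation. Epcam and Cftr rose (3.16 ± 0.35 and 4.70 ± 0.67), and Aqp1 fell (-0.77 ± 0.15). Of the 25 collagen and fibrillar matrix genes, 18 rose and 1 fell (19 and 1 adjusted over the list alone), with a median log2 fold change of 0.85 and an adjusted p = 0.4 with an estimated correlation. Col1a1 and Col3a1 rose (1.75 ± 0.33 and 1.56 ± 0.30), and fibronectin, Fn1, fell (-1.62 ± 0.20). Of the 19 genes of matrix proteases and their inhibitors, 7 rose and 2 fell (7 and 2 adjusted over the list alone), with a median log2 fold change of 0.53 and an adjusted p = 0.4 with an estimated correlation. Mmp7 and Mmp13 rose (5.10 ± 0.67 and 3.54 ± 0.50). Of the 20 stellate cell and myofibroblast markers, 5 rose and 1 fell (3 and 0 adjusted over the list alone), with a median log2 fold change of 0.27. Of the 17 sinusoidal endothelial markers, 0 rose and 16 fell (0 and 17 adjusted over the list alone), with a median log2 fold change of -0.96 and an adjusted p = 0.21 with an estimated correlation. Kdr and Clec4g fell (-1.33 ± 0.18 and -1.17 ± 0.15). Of the 12 Kupffer cell markers, 0 rose and 7 fell (0 and 7 adjusted over the list alone), with a median log2 fold change of -1.03 and an adjusted p = 0.4 with an estimated correlation. Marco and Timd4 fell (-3.18 ± 0.74 and -2.19 ± 0.38). Of the 11 B and plasma cell markers, 0 rose and 8 fell (0 and 8 adjusted over the list alone), with a median log2 fold change of -1.26 and an adjusted p = 0.323 with an estimated correlation. Cd79a fell (-2.74 ± 0.46). Of the 15 T and NK cell markers, 0 rose and 4 fell (0 and 4 adjusted over the list alone), with a median log2 fold change of -0.63. Of the 21 monocyte and macrophage markers, 6 rose and 5 fell (6 and 5 adjusted over the list alone), with a median log2 fold change of -0.15. Trem2 rose (2.16 ± 0.32) and the mannose receptor gene Mrc1 fell (-0.79 ± 0.18). Of the 12 neutrophil markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with a median log2 fold change of -0.02. Of the 20 chemokine and cytokine genes, 3 rose and 6 fell (3 and 7 adjusted over the list alone), with a median log2 fold change of -0.43. Cxcl13 and Cxcl1 fell (-5.29 ± 1.00 and -2.47 ± 0.54). Of the 12 erythroid and platelet markers, 1 rose and 0 fell (0 and 0 adjusted over the list alone), with a median log2 fold change of 0.83. Of the 6 mesothelium and other-organ markers, 3 rose and 0 fell (3 and 1 adjusted over the list alone), with a median log2 fold change of 0.74. Krt8, a keratin also of hepatocytes, rose (1.90 ± 0.26). Cftr (8.90 without 12 replicate 3), Mmp7 (6.72 without 12 replicate 2), Marco (-4.21 without 12ON replicate 1), Cxcl13 (-4.51 without 12 replicate 1, -6.07 without 12ON replicate 1) and Cxcl1 (-3.07 without 12ON replicate 1) moved by over 1.5 times in fold. Genes of matrix proteases and their inhibitors had a median of 0.28 without 12 replicate 1 (camera adjusted p = 0.0867), 0.59 without 12ON replicate 1 (camera adjusted p = 0.0533) and 0.35 without 12ON replicate 2.

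Over the 40 lists, camera with a preset correlation of 0.01 called 12 up and 12 down, and with an estimated correlation it called 0, the smallest value being adjusted p = 0.21 with an estimated correlation. Fry, which tests whether the genes of a list move on balance in 1 direction, called 23 of those 24.

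**Figure D3:**
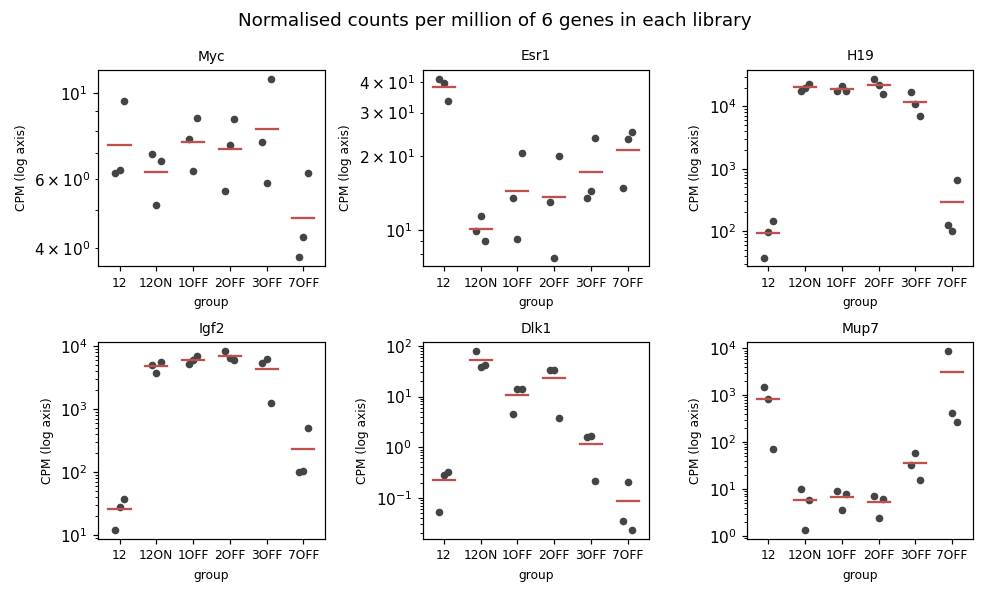
Normalised CPM of Myc, Esr1, H19, Igf2, Dlk1 and Mup7 in each of 18 libraries on log axes, by group, with points for mice and red lines for group means. H19 averaged 93.1 CPM in group 12 and 20260 CPM in 12ON, and Mup7 reached 8853 CPM in 7OFF replicate 1.

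The second comparison set each OFF group against 12ON. In 1OFF, the lists of G1/S, mitosis and ribosome biogenesis had medians below 12ON and that of secreted hepatocyte proteins above it, and camera called 0 lists with an estimated correlation. H19 and Igf2 are followed here because they led the first comparison. Over all genes, edgeR's quasi-likelihood test called 1 gene higher, the unnamed locus Gm26714 (log2 1.81 ± 0.25, adjusted p = 0.039), which was looked up after its value was seen, and 0 lower. At an unadjusted p under 0.05 there were 2568 genes, where 889 were expected by chance, and DESeq2 called 125 higher and 389 lower. The 30 G1/S and DNA replication genes had a median log2 fold change of -1.09, with 0 members higher and 24 lower adjusted over the list alone and an adjusted p = 0.124 with an estimated correlation. Cdt1 and Mcm7 had -1.16 ± 0.25 and -1.16 ± 0.24. The 30 mitosis genes lay at a median of 2.14 times below 12ON, with 0 members higher and 27 lower adjusted over the list alone and an adjusted p = 0.326 with an estimated correlation. Anln and Kif11 had -1.24 ± 0.37 and -1.23 ± 0.38. The 44 canonical MYC targets had a median log2 fold change of -0.33, with 0 members higher and 21 lower adjusted over the list alone and an adjusted p = 0.263 with an estimated correlation. The 42 ribosome biogenesis genes had a median log2 fold change of -0.31, with 0 members higher and 21 lower adjusted over the list alone and an adjusted p = 0.271 with an estimated correlation. Nolc1 and Dkc1 had -0.68 ± 0.13 and -0.46 ± 0.10. The 25 nucleotide synthesis genes had a median log2 fold change of -0.38, with 0 members higher and 12 lower adjusted over the list alone and an adjusted p = 0.124 with an estimated correlation. The 25 secreted hepatocyte protein genes had a median log2 fold change of 0.45, with 1 member higher and 0 lower adjusted over the list alone and an adjusted p = 0.263 with an estimated correlation. The 20 periportal genes had a median log2 fold change of 0.55, with 2 members higher and 0 lower adjusted over the list alone and an adjusted p = 0.263 with an estimated correlation. Pigr had 1.61 ± 0.38. The 17 sinusoidal endothelial markers had a median log2 fold change of 0.26, with 3 members higher and 0 lower adjusted over the list alone and an adjusted p = 0.326 with an estimated correlation. The 14 fetal liver genes had a median log2 fold change of -0.57, with 0 members higher and 1 lower adjusted over the list alone and an adjusted p = 0.557 with an estimated correlation. Dlk1 had -2.30 ± 0.67, H19 -0.09 ± 0.59 and Igf2 0.35 ± 0.60. Myc and Esr1 had 0.26 ± 0.25 and 0.50 ± 0.33, and neither passed. Gm26714 no longer passed without 12ON replicate 1, 2 or 3 or 1OFF replicate 1, 2 or 3 (adjusted p from 0.0934 to 0.454). Fetal liver genes had a median of -0.44 without 1OFF replicate 3 (camera adjusted p = 0.0683).

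In 2OFF the lists of G1/S, mitosis, MYC targets, ribosome biogenesis and nucleotide synthesis had medians below 12ON and that of secreted hepatocyte proteins above it. Camera called 0 lists with an estimated correlation, and no gene passed over all genes. The edgeR test called 0 genes higher and 0 lower, with a smallest adjusted p = 0.0503 and 3039 genes at an unadjusted p under 0.05, and DESeq2 called 269 higher and 650 lower. Without 2OFF replicate 2, edgeR called 520 higher and 985 lower. That library lay within the range of 12ON in mean log2 CPM of the mitosis list over group 12 (2.62, against 2.56 to 3.30 in 12ON and 1.70 and 0.48 in the other 2OFF libraries) and on the first principal component (60.6, against 55.4 to 73.6, and 36.7 and 16.5). For the G1/S list it had 1.35, against 1.55 to 1.95 in 12ON and 0.26 and 0.20 in the other 2OFF libraries. The 30 G1/S and DNA replication genes had a median log2 fold change of -1.15, with 0 members higher and 26 lower adjusted over the list alone and an adjusted p = 0.0624 with an estimated correlation. Pcna and Rfc4 had -0.95 ± 0.18 and -1.08 ± 0.20. The 30 mitosis genes had a median log2 fold change of -1.19, with 0 members higher and 30 lower adjusted over the list alone and an adjusted p = 0.305 with an estimated correlation. The 44 canonical MYC targets had a median log2 fold change of -0.41, with 0 members higher and 31 lower adjusted over the list alone and an adjusted p = 0.137 with an estimated correlation. The 42 ribosome biogenesis genes had a median log2 fold change of -0.35, with 0 members higher and 35 lower adjusted over the list alone and an adjusted p = 0.204 with an estimated correlation. The 25 nucleotide synthesis genes had a median log2 fold change of -0.48, with 0 members higher and 16 lower adjusted over the list alone and an adjusted p = 0.0624 with an estimated correlation. Dut had -0.83 ± 0.14. The 15 cholangiocyte markers had a median log2 fold change of -0.95, with 0 members higher and 7 lower adjusted over the list alone and an adjusted p = 0.305 with an estimated correlation. Krt19 and Krt7 had -1.40 ± 0.35 and -0.95 ± 0.25. The 18 drug-metabolism genes had a median log2 fold change of -0.49, with 0 members higher and 4 lower adjusted over the list alone and an adjusted p = 0.381 with an estimated correlation. Cyp2b10 had -2.74 ± 0.68. The 25 secreted hepatocyte protein genes had a median log2 fold change of 0.43, with 0 members higher and 0 lower adjusted over the list alone and an adjusted p = 0.305 with an estimated correlation. H19 and Igf2 had 0.12 ± 0.59 and 0.55 ± 0.60. Myc and Esr1 had 0.20 ± 0.25 and 0.42 ± 0.33, and neither passed. Mitosis genes had a median of -1.81 without 2OFF replicate 2.

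In 3OFF, most members of the mitosis and ribosome biogenesis lists were below 12ON and most secreted hepatocyte protein genes above it, and as lists they had an adjusted p = 0.181 or more with an estimated correlation. The test called 2726 genes higher and 3028 lower. The highest were Cyp2c39 (5.27 ± 1.48), Dbp (4.39 ± 1.23), Ciart (3.74 ± 1.12), Mmd2 (3.66 ± 0.71), Serpina3k (3.58 ± 0.77) and Slc1a2 (3.54 ± 0.68), and the lowest Dlk1 (-5.48 ± 0.80), Fabp6 (-5.27 ± 1.80), Jag2 (-5.14 ± 0.61), Bex1 (-3.97 ± 0.67), Ggt1 (-3.83 ± 0.75) and Esco2 (-3.69 ± 0.49). Cyp2c39 lay at 151 to 193 CPM in 3OFF, but also at 214 CPM in 12 replicate 3 and 184 CPM in 2OFF replicate 3. In all other libraries it lay at 2.73 to 12.6 CPM, so its value may reflect differences between mice. Dbp and Ciart are clock-controlled, and the labels do not give the hour of sampling. Without 12ON replicate 2 the count of higher genes was 1528, and in libraries with low Xist alone it was 763, with 1209 lower. H19 had -0.79 ± 0.60 (adjusted p = 0.332). Myc and Esr1 had 0.37 ± 0.25 and 0.76 ± 0.33, and neither passed. Serpina3k (4.23 without 12ON replicate 1), Fabp6 (-4.41 without 12ON replicate 2, -7.79 without 3OFF replicate 1), Jag2 (-5.75 without 3OFF replicate 1), Bex1 (-4.62 without 3OFF replicate 1) and Ggt1 (-4.64 without 3OFF replicate 1) moved by over 1.5 times in fold. Cyp2c39 no longer passed without 12ON replicate 2 (adjusted p = 0.061), Dbp without 12ON replicate 2 (adjusted p = 0.0547), Ciart without 12ON replicate 1, 2 or 3 or 3OFF replicate 3 (adjusted p from 0.0528 to 0.0712) and Fabp6 without 12ON replicate 2 or 3OFF replicate 2 or 3 (adjusted p from 0.107 to 0.11).

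Of the 44 canonical MYC targets, 1 rose and 35 fell (1 and 36 adjusted over the list alone), with a median log2 fold change of -0.82 and an adjusted p = 0.181 with an estimated correlation. The gene of the RAN-binding protein, Ranbp1, fell (-1.23 ± 0.14). Of the 42 ribosome biogenesis genes, 0 rose and 40 fell (0 and 42 adjusted over the list alone), with a median log2 fold change of -0.67 and an adjusted p = 0.181 with an estimated correlation. Of the 30 ribosomal protein genes, 0 rose and 18 fell (0 and 25 adjusted over the list alone), with a median log2 fold change of -0.37 and an adjusted p = 0.543 with an estimated correlation. Of the 25 nucleotide synthesis genes, 1 rose and 18 fell (2 and 19 adjusted over the list alone), with a median log2 fold change of -0.69 and an adjusted p = 0.181 with an estimated correlation. Of the 30 G1/S genes, 1 rose and 25 fell (1 and 26 adjusted over the list alone), with a median log2 fold change of -1.92 and an adjusted p = 0.181 with an estimated correlation. Of the 30 mitosis genes, 0 rose and 30 fell (0 and 30 adjusted over the list alone), with a median log2 fold change of -2.82 and an adjusted p = 0.195 with an estimated correlation. Ttk and Hmmr fell (-3.55 ± 0.49 and -3.61 ± 0.46). Of the 25 secreted hepatocyte protein genes, 20 rose and 0 fell (22 and 0 adjusted over the list alone), with a median log2 fold change of 0.87 and an adjusted p = 0.195 with an estimated correlation. Ttr and Itih1 rose (1.19 ± 0.22 and 1.84 ± 0.31). Of the 20 perivenous genes, 11 rose and 1 fell (13 and 1 adjusted over the list alone), with a median 2.14 times higher and an adjusted p = 0.338 with an estimated correlation. Cyp2e1, the enzyme that activates carbon tetrachloride, rose (2.80 ± 0.48), as did Glul (1.24 ± 0.23). Of the 20 bile acid and sterol genes, 9 rose and 0 fell (10 and 0 adjusted over the list alone), with a median log2 fold change of 1.02 and an adjusted p = 0.195 with an estimated correlation. Abcg5 and Abcg8, the sterol exporter, rose (2.01 ± 0.36 and 2.16 ± 0.37). Of the 25 gluconeogenesis and amino acid genes, 21 rose and 1 fell (22 and 1 adjusted over the list alone), with a median 2.14 times higher and an adjusted p = 0.25 with an estimated correlation. Of the 24 cholesterol synthesis genes, 3 rose and 2 fell (3 and 1 adjusted over the list alone), with a median log2 fold change of 0.04. Of the 24 acute phase genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone), with a median log2 fold change of 1.06 and an adjusted p = 0.543 with an estimated correlation. Of the 25 collagen and matrix genes, 1 rose and 9 fell (1 and 12 adjusted over the list alone), with a median log2 fold change of -0.56 and an adjusted p = 0.547 with an estimated correlation. Of the 17 sinusoidal endothelial markers, 14 rose and 0 fell (14 and 0 adjusted over the list alone), with a median log2 fold change of 0.60 and an adjusted p = 0.25 with an estimated correlation. Of the 12 Kupffer cell markers, 5 rose and 0 fell (9 and 0 adjusted over the list alone), with a median log2 fold change of 0.67 and an adjusted p = 0.398 with an estimated correlation. Of the 14 fetal liver genes, 0 rose and 9 fell (0 and 9 adjusted over the list alone), with a median log2 fold change of -1.46 and an adjusted p = 0.25 with an estimated correlation. Of the 15 clock genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone), with a median log2 fold change of 1.19 and an adjusted p = 0.25 with an estimated correlation. Per2 and Tef rose (2.19 ± 0.47 and 2.52 ± 0.62).

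In 7OFF, most members of the fetal and mitosis lists were below 12ON and most secreted hepatocyte protein genes above it, and as lists they had an adjusted p = 0.241 with an estimated correlation. The test called 3801 genes higher and 4032 lower. H19 fell by 6.09 ± 0.74 on the log2 scale, and Dlk1 by 9.09 ± 1.08. Other lowest genes were Fabp6 (-7.59 ± 2.31), Styk1 (-7.35 ± 1.01), Gpx6 (-6.71 ± 0.60), Mir675 (-6.20 ± 0.75) and Cacna1b (-6.14 ± 0.55). The highest were the Mup genes Mup7 (9.10 ± 1.59), Mup15 (8.47 ± 1.42), Mup17 (8.45 ± 1.46), Mup1 (8.26 ± 1.39), Mup12 (8.25 ± 1.37) and Mup14 (8.18 ± 1.39), which are uncertain as near-identical copies. Their folds rest largely on 7OFF replicate 1: Mup7 lay at 8853 CPM there and at 429 and 272 CPM in replicates 2 and 3, Mup15 at 5034 against 366 and 233 CPM, and Mup1 at 4603 against 434 and 280 CPM. Esr1 rose (1.06 ± 0.33, adjusted p = 0.0163), and Myc did not pass (-0.39 ± 0.26, adjusted p = 0.23). H19 (-7.49 without 7OFF replicate 3), Dlk1 (-10.75 without 7OFF replicate 2), Fabp6 (-6.72 without 12ON replicate 2), Mir675 (-7.59 without 7OFF replicate 3), Cacna1b (-6.78 without 7OFF replicate 3) and the 6 Mup genes (8.90 to 9.75 without 12ON replicate 1 in 5 of them, 5.82 to 6.12 without 7OFF replicate 1) moved by over 1.5 times in fold. Fabp6 no longer passed without 7OFF replicate 2 (adjusted p = 0.0521) and Esr1 without 12ON replicate 3 or 7OFF replicate 3 (adjusted p from 0.0557 to 0.0591).

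Of the 44 canonical MYC targets, 2 rose and 37 fell (2 and 37 adjusted over the list alone), with a median log2 fold change of -0.84 and an adjusted p = 0.241 with an estimated correlation. Of the 42 ribosome biogenesis genes, 1 rose and 36 fell (1 and 36 adjusted over the list alone), with a median log2 fold change of -0.69 and an adjusted p = 0.244 with an estimated correlation. Of the 30 ribosomal protein genes, 0 rose and 30 fell (0 and 30 adjusted over the list alone), with a median log2 fold change of -0.72 and an adjusted p = 0.335 with an estimated correlation. Of the 30 G1/S genes, 1 rose and 26 fell (1 and 28 adjusted over the list alone), with a median log2 fold change of -2.18 and an adjusted p = 0.241 with an estimated correlation. Of the 30 mitosis genes, 0 rose and 30 fell (0 and 30 adjusted over the list alone), with a median log2 fold change of -3.90 and an adjusted p = 0.241 with an estimated correlation. Cdk1 and Foxm1 fell (-4.06 ± 0.44 and -3.67 ± 0.42). Of the 25 secreted hepatocyte protein genes, 20 rose and 0 fell (23 and 0 adjusted over the list alone), with a median log2 fold change of 1.03 and an adjusted p = 0.241 with an estimated correlation. Apoc3 and Apoa2 rose (1.61 ± 0.14 and 1.44 ± 0.17). Of the 20 perivenous genes, 15 rose and 1 fell (15 and 1 adjusted over the list alone), with a median log2 fold change of 1.23 and an adjusted p = 0.335 with an estimated correlation. Of the 20 bile acid and sterol genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone), with a median log2 fold change of 0.97 and an adjusted p = 0.244 with an estimated correlation. Slco1a1 rose (5.64 ± 0.81). Of the 18 fatty acid synthesis genes, 9 rose and 0 fell (9 and 1 adjusted over the list alone), with a median log2 fold change of 0.71 and an adjusted p = 0.335 with an estimated correlation. Mlxipl and Srebf1, transcription factors of lipid synthesis, rose (1.46 ± 0.15 and 1.36 ± 0.19). Of the 24 cholesterol synthesis genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone), with a median log2 fold change of 0.22 and an adjusted p = 0.606 with an estimated correlation. Of the 25 collagen and matrix genes, 1 rose and 15 fell (1 and 15 adjusted over the list alone), with a median log2 fold change of -0.79 and an adjusted p = 0.415 with an estimated correlation. Col1a1 and Col4a1 fell (-1.61 ± 0.32 and -1.37 ± 0.18). Of the 19 matrix protease genes, 1 rose and 8 fell (1 and 8 adjusted over the list alone), with a median log2 fold change of -0.47 and an adjusted p = 0.335 with an estimated correlation. Mmp7 fell (-4.72 ± 0.61). Of the 21 monocyte and macrophage markers, 0 rose and 10 fell (0 and 10 adjusted over the list alone), with a median log2 fold change of -0.63 and an adjusted p = 0.335 with an estimated correlation. Cd68 and Lgals3 fell (-1.04 ± 0.14 and -1.44 ± 0.17). Of the 12 erythroid and platelet markers, 1 rose and 10 fell (1 and 10 adjusted over the list alone), with a median log2 fold change of -2.13 and an adjusted p = 0.427 with an estimated correlation. The globin genes Hba-a1 and Hbb-bs had -2.13 ± 0.52 and -2.28 ± 0.53. Of the 14 fetal liver genes, 0 rose and 12 fell (0 and 13 adjusted over the list alone), with a median log2 fold change of -2.41 and an adjusted p = 0.241 with an estimated correlation. Bex2 and Igf2bp3 fell (-4.84 ± 0.60 and -3.53 ± 0.49). Of the 11 B and plasma cell markers, 6 rose and 0 fell (6 and 0 adjusted over the list alone), with a median log2 fold change of 1.13 and an adjusted p = 0.335 with an estimated correlation. Of the 18 sex-biased liver genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone), with a median log2 fold change of 2.27 and an adjusted p = 0.244 with an estimated correlation. Slco1a1 (4.88 without 7OFF replicate 1) moved by over 1.5 times in fold. Cholesterol synthesis genes had a median of 0.08 without 12ON replicate 2 (camera adjusted p = 0.0903), 0.48 without 12ON replicate 3, 0.35 without 7OFF replicate 2 and 0.15 without 7OFF replicate 3 (camera adjusted p = 0.0876). Matrix protease genes had a median of -0.73 without 7OFF replicate 3. Erythroid and platelet markers had a median of -1.40 without 12ON replicate 3. B and plasma cell markers had a median of 0.71 without 12ON replicate 2. Sex-biased liver genes had a median of 2.02 without 12ON replicate 3 (camera adjusted p = 0.0614) and 1.15 without 7OFF replicate 1.

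Camera with a preset correlation called 17, 15, 23 and 28 of the 40 lists in 1OFF, 2OFF, 3OFF and 7OFF against 12ON, and with an estimated correlation it called 0 in each, the smallest values being adjusted p = 0.124, adjusted p = 0.0624, adjusted p = 0.181 and adjusted p = 0.241 with an estimated correlation. Fry called 5, 4, 20 and 26 of the called lists.

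Genes that changed in 12ON vs 12 were followed through the OFF groups. Of the 4269 genes higher in 12ON, 0, 0, 2469 and 3194 were lower than 12ON in 1OFF, 2OFF, 3OFF and 7OFF. Of the 4029 lower genes, 1, 0, 2080 and 2813 were higher than 12ON. By DESeq2 the counts were 370 and 111 in 1OFF and 594 and 217 in 2OFF, and without 2OFF replicate 2 edgeR gave 904 and 432 in 2OFF. In libraries with low Xist alone they were 1056 and 599 in 3OFF and 2236 and 1767 in 7OFF, and without 12ON replicate 2 the lower genes counted 1179 in 3OFF. The 12ON libraries enter both comparisons, and groups simulated as unchanged from 12ON gave at most 1 such gene, while groups simulated as equal to group 12 gave means of 3599 and 3329 genes at 3OFF. In runs unchanged from 12ON almost no gene is called, so they do not measure what shared libraries add where many genes change. Independent lists of the observed sizes would share 727 and 617 genes at 3OFF and 968 and 861 at 7OFF. Part of the excess may come from the shared libraries.

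Against group 12, the mitosis and fetal lists had high medians and the secreted hepatocyte list a low one in 1OFF and 2OFF, and fewer genes differed in 3OFF and 7OFF. The counts of higher and lower genes were 3036 and 2903 in 1OFF, 3218 and 3018 in 2OFF, 1685 and 1414 in 3OFF, and 439 and 588 in 7OFF. The mitochondrial share of no OFF group overlapped that of group 12. With a term for it the counts were 1168 and 680, 1202 and 698, 491 and 240, and 182 and 235. Which part of the difference goes with that share stays open. H19 was higher than in group 12 in 1OFF (7.68 ± 0.80) and in 3OFF (6.98 ± 0.77), and Igf2 in 7OFF (3.18 ± 0.65). Of the 30 mitosis genes in 1OFF, 29 rose and 0 fell (30 and 0 adjusted over the list alone), with a median log2 fold change of 1.94 and an adjusted p = 0.426 with an estimated correlation. Of the 25 secreted hepatocyte protein genes in 1OFF, 0 rose and 19 fell (0 and 20 adjusted over the list alone), with a median log2 fold change of -0.70 and an adjusted p = 0.323 with an estimated correlation. Of the 30 mitosis genes in 2OFF, 28 rose and 0 fell (30 and 0 adjusted over the list alone), with a median log2 fold change of 1.99 and an adjusted p = 0.423 with an estimated correlation. Of the 25 secreted hepatocyte protein genes in 2OFF, 0 rose and 18 fell (0 and 20 adjusted over the list alone), with a median log2 fold change of -0.74 and an adjusted p = 0.359 with an estimated correlation. Of the 14 fetal liver genes in 1OFF, 10 rose and 0 fell (10 and 0 adjusted over the list alone), with a median log2 fold change of 2.20 and an adjusted p = 0.323 with an estimated correlation. Of the 14 fetal liver genes in 2OFF, 12 rose and 0 fell (12 and 0 adjusted over the list alone), with a median log2 fold change of 2.51 and an adjusted p = 0.359 with an estimated correlation. Of the 30 mitosis genes in 3OFF, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with a median log2 fold change of 0.24. Of the 30 ribosomal protein genes in 3OFF, 28 rose and 0 fell (29 and 0 adjusted over the list alone), with a median log2 fold change of 0.53 and an adjusted p = 0.743 with an estimated correlation. Of the 24 cholesterol synthesis genes in 3OFF, 0 rose and 21 fell (0 and 21 adjusted over the list alone), with a median log2 fold change of -1.09 and an adjusted p = 0.651 with an estimated correlation. Sqle and Cyp51 fell (-1.58 ± 0.23 and -1.50 ± 0.24). Of the 20 unfolded protein response genes in 3OFF, 0 rose and 13 fell (0 and 15 adjusted over the list alone), with a median log2 fold change of -0.91 and an adjusted p = 0.743 with an estimated correlation. Of the 24 cholesterol synthesis genes in 7OFF, 0 rose and 13 fell (0 and 15 adjusted over the list alone), with a median log2 fold change of -0.81 and an adjusted p = 0.436 with an estimated correlation. Sqle and Mvk fell (-1.46 ± 0.23 and -1.06 ± 0.19). Of the 21 macrophage markers in 7OFF, 0 rose and 10 fell (0 and 11 adjusted over the list alone), with a median log2 fold change of -0.77 and an adjusted p = 0.436 with an estimated correlation. C1qb and Cd68 fell (-0.81 ± 0.17 and -0.77 ± 0.14). Of the 12 Kupffer cell markers in 7OFF, 0 rose and 6 fell (0 and 10 adjusted over the list alone), with a median log2 fold change of -0.93 and an adjusted p = 0.436 with an estimated correlation. Of the 24 acute phase genes in 7OFF, 0 rose and 9 fell (0 and 17 adjusted over the list alone), with a median log2 fold change of -1.69 and an adjusted p = 0.436 with an estimated correlation. Orm2 and Il1rn fell (-2.89 ± 0.55 and -1.79 ± 0.28). In 3OFF vs 12, edgeR called 1113 higher without 12 replicate 1 and 1044 higher without 3OFF replicate 1, and 922 lower without 12 replicate 2, 743 lower without 3OFF replicate 1 and 938 lower without 3OFF replicate 3. A fit of groups 3OFF and 12 alone called 1029 higher and 859 lower. Leaving out any library of groups 7OFF and 12 but 7OFF replicate 3 lowered the count of higher genes by over 1.5 times, to 133 without replicate 1 of group 12, and replicates 1 and 2 of either group did so for lower genes, to 187 without 7OFF replicate 1. A fit of groups 7OFF and 12 alone called 45 higher and 171 lower. Igf2 (1.99 without 7OFF replicate 3) moved by over 1.5 times in fold. Igf2 no longer passed without 12 replicate 1 (adjusted p = 0.0564) and C1qb without 12 replicate 1 or 7OFF replicate 1 (adjusted p from 0.0509 to 0.0541). Mitosis genes in 2OFF had a median of 1.31 without 2OFF replicate 2. Unfolded protein response genes in 3OFF had a median of -0.44 without 12 replicate 2.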

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

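The comparison of 7OFF with 1OFF and the splits of the libraries were planned. The test of other imprinted genes followed the rise of H19, Igf2 and Dlk1, with its limits set before its own result was seen. The other tests here were chosen only after the result was seen. The OFF groups differed from 12ON to different degrees, tested as 7OFF against 1OFF by edgeR's quasi-likelihood test: 2640 genes were higher and 2806 lower in 7OFF. Among the named genes, the log2 fold changes of those higher in 7OFF were Mmd2 (2.18), Serpina3k (3.47) and Slc1a2 (2.79), and of the Mup genes Mup7 (8.84), Mup15 (8.32), Mup17 (8.34), Mup1 (8.17), Mup12 (8.20) and Mup14 (8.04). Without 7OFF replicate 1 the Mup genes had 5.65 to 6.01 and Serpina3k 2.84, without 1OFF replicate 3 Serpina3k had 4.57, and without 1OFF replicate 1 or 2 or 7OFF replicate 3 Mmd2 no longer passed (adjusted p from 0.0533 to 0.0897). Those lower in 7OFF were Dlk1 (-6.80), Jag2 (-4.25), Bex1 (-3.08), Ggt1 (-3.89), Esco2 (-3.35), Styk1 (-7.10), Gpx6 (-5.78), Mir675 (-6.11) and Cacna1b (-5.13), with Dlk1 at -8.45 without 7OFF replicate 2, Ggt1 at -3.18 without 1OFF replicate 2, and Mir675 at -7.50 and Cacna1b at -5.77 without 7OFF replicate 3.

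Few genes passed against 12ON at 1OFF and 2OFF, and an absence of any change is argued against by 24 of 30 G1/S members lower in 1OFF, adjusted over the list alone, although the list had an adjusted p = 0.124 with an estimated correlation. For 2OFF, 1505 genes passed without 2OFF replicate 2 and 0 without either of the other 2OFF libraries. Leaving it out also moved the group away from 12ON, with the mitosis median going from -1.188 to -1.810. A library that widens the spread may thus account for 2OFF, but cannot be told apart from one that brings the group nearer to 12ON. That library lay within the range of 12ON in the mitosis list (2.62, against 2.56 to 3.30) and on the first principal component (60.6, against 55.4 to 73.6), but below it in the lists of G1/S (1.35, against 1.55 to 1.95), MYC targets (0.66, against 0.82 to 1.04) and ribosome biogenesis (0.67, against 0.77 to 1.01). For 1OFF, a spread shared over all 6 groups may add to it, since a fit of the 2 groups alone called 189 genes. For 2OFF that fit called 0 by edgeR, but it kept 2OFF replicate 2, so it cannot tell whether the shared spread matters there. DESeq2 called 269 higher and 650 lower in 2OFF.

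Of the mitosis genes 30 of 30 were higher, and of the secreted hepatocyte protein genes 23 of 25 lower, in 12ON than in group 12, with an adjusted p = 0.21 or more for lists with an estimated correlation. A scaling factor cancels out of the gap between these lists within a library, and the lowest gap in 12ON lay 3.613 above the highest in group 12 (log2), which argues against scaling as the whole cause, as do 5988 genes passing in libraries with low Xist alone against the mix of high-Xist and low-Xist libraries. A lower share of hepatocytes, with the other cell types in unchanged proportions, would raise the markers of all of them. That form is argued against by 16 of 17 sinusoidal endothelial markers lower (median -0.956) and 9 of 15 cholangiocyte markers higher. Camera called 0 of 9 such lists with an estimated correlation. A growing share of 1 other cell type would lower the rest together with hepatocytes, so a lower share of hepatocytes stays open. With a term for the mitochondrial share 28 mitosis genes passed, their median going from 3.164 to 2.333 and their median error from 0.486 to 0.671, which argues against RNA quality that follows it as their whole cause, but 10 secreted hepatocyte protein genes did, their median going from -1.197 to -0.841 and their median error from 0.205 to 0.301, which leaves it open there. Tamoxifen apart from MycER cannot be told apart from activation, as no label names a group given tamoxifen alone, and 8 drug-metabolism genes were higher in 12ON.

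H19, Igf2 and Dlk1 were over 100-fold higher in 12ON. H19 held at least 17.9 times the counts of Mir675, a short gene within it, in each 12ON library. Most H19 counts therefore did not come from reads over Mir675. A high ratio follows from the lengths of the 2 genes and does not bear on why H19 rose. Whether imprinted genes rose as a group was not decided by the limits set beforehand. Of 23 other imprinted genes 6 were higher and 2 lower, beside 4269 higher and 4029 lower of all 17789 genes tested. Their median of -0.045, with a camera p = 0.667 at the preset correlation, argues against a rise of these 23 as a whole. The activation that the groups name stays among the open explanations.

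The 6 libraries of each comparison allow 10 splits, too few for a share under 0.05. In fits of the 2 groups alone, the real split called 8096 genes in 12ON vs 12, 6187 in 3OFF vs 12ON, 6841 in 7OFF vs 12ON, 5718 in 1OFF vs 12, 4287 in 2OFF vs 12, 1888 in 3OFF vs 12 and 4214 in 7OFF vs 1OFF, and the highest other split 0 in each. It called 189 in 1OFF vs 12ON and 216 in 7OFF vs 12, with 2 in the highest other split of each. In 2OFF vs 12ON it called 0, as did each of the 10 splits, and in the other comparisons 1 of 10 splits gave as many genes as the real one, the real one itself.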

How the results depend on the processing

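The sex term, the mitochondrial share term, the libraries with low Xist alone and the renumbering of libraries were chosen only after the result was seen, and the other alternatives were planned. For results that changed, the cause was not tested. No result turned into a call in the other direction under any alternative run, but leaving out 1 library changed the sign of the median of 2 called lists as their calls ended. These were cholesterol synthesis in 1OFF vs 12ON (0.14 to -0.02 without 12ON replicate 2) and the unfolded protein response in 7OFF vs 12 (-0.34 to 0.18 without 12 replicate 2).

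Tested against a 1.5-fold change, the counts were 1637 higher and 1255 lower in 12ON vs 12, 0 higher and 0 lower in 1OFF vs 12ON, 280 higher and 686 lower in 3OFF vs 12ON, 960 higher and 1402 lower in 7OFF vs 12ON and 875 higher and 542 lower in 1OFF vs 12. They were 926 higher and 627 lower in 2OFF vs 12, 199 higher and 122 lower in 3OFF vs 12, 16 higher and 23 lower in 7OFF vs 12 and 293 higher and 641 lower in 7OFF vs 1OFF. Of the genes higher and lower in 12ON vs 12, those changing the other way were 0 and 0 in 1OFF, 615 and 218 in 3OFF and 1119 and 642 in 7OFF. At an adjusted p threshold of 0.01 the counts were 0 higher and 0 lower in 1OFF vs 12ON, 1415 higher and 1833 lower in 3OFF vs 12ON, 1897 higher and 1602 lower in 1OFF vs 12, 2078 higher and 1760 lower in 2OFF vs 12 and 728 higher and 521 lower in 3OFF vs 12. They were 65 higher and 114 lower in 7OFF vs 12 and 1332 higher and 1682 lower in 7OFF vs 1OFF, with 0 and 0 in 1OFF, 1545 and 1072 in 3OFF and 2278 and 1817 in 7OFF changing the other way.

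DESeq2 called 125 higher and 389 lower in 1OFF vs 12ON, 269 higher and 650 lower in 2OFF vs 12ON and 733 higher and 935 lower in 7OFF vs 12, with 370 and 111 in 1OFF and 594 and 217 in 2OFF changing the other way. Fits of the 2 groups alone called 46 higher and 143 lower in 1OFF vs 12ON, 1029 higher and 859 lower in 3OFF vs 12 and 45 higher and 171 lower in 7OFF vs 12. With the 20 most abundant genes left out of library sizes there were 5 higher and 42 lower in 2OFF vs 12ON and 42 and 5 in 2OFF changing the other way. With a stricter filter there were 33 higher and 158 lower in 2OFF vs 12ON and 155 and 31 in 2OFF changing the other way. Other scalings moved the median of all genes by at most 0.027 on the log2 scale.

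A replicate block, with the replicate number of the labels as a term, gave 4 higher and 14 lower in 1OFF vs 12ON and 93 higher and 346 lower in 2OFF vs 12ON, with 14 and 4 in 1OFF and 333 and 79 in 2OFF changing the other way. It changed the call of 2 of 200 list results and of 0 of the 58 named-gene results, and no other count moved by over 1.5 times. The labels do not say that a number marks a shared litter, batch or day, and not every pair of libraries with the same number correlated above 0.1 (from -0.18 to 0.334 over 45 pairs, with a mean of 0.0302, against -0.0153 for other numbers), so pairing was not taken as given. As a hint from the data, 11 of 18 libraries correlated best with their own number, where 6 were expected, and 6.88% of 7776 renumberings within groups gave as many.

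With a sex term there were 0 genes higher in 1OFF vs 12ON and 0 changing the other way. Libraries with low Xist alone gave 0 higher and 0 lower in 1OFF vs 12ON, 763 higher and 1209 lower in 3OFF vs 12ON, 2260 higher and 1979 lower in 2OFF vs 12, 933 higher and 745 lower in 3OFF vs 12 and 239 higher and 315 lower in 7OFF vs 12. In them 0 and 0 in 1OFF, 1056 and 599 in 3OFF and 2236 and 1767 in 7OFF changed the other way.

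With a term for the mitochondrial share the counts were 2327 higher and 1788 lower in 12ON vs 12, 1168 higher and 680 lower in 1OFF vs 12, 1202 higher and 698 lower in 2OFF vs 12, 491 higher and 240 lower in 3OFF vs 12 and 182 higher and 235 lower in 7OFF vs 12, with 0 higher in 1OFF vs 12ON and 1475 higher in 7OFF vs 1OFF. Of the genes changing the other way there were 0 of the lower ones in 1OFF, 1132 of the lower ones in 3OFF, and 1985 and 1401 in 7OFF.

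Leaving out 1 library at a time gave 0 in each case for genes higher in 1OFF vs 12ON. It gave 0 (without 12ON replicate 2) to 520 (without 2OFF replicate 2) higher and 0 (without 12ON replicate 2) to 985 (without 2OFF replicate 2) lower in 2OFF vs 12ON. Besides 2OFF replicate 2, 12ON replicate 1 gave 2 higher and 20 lower when left out, and 12ON replicate 3 gave 1 lower. The count of higher genes in 3OFF vs 12ON was 1528 (without 12ON replicate 2) to 2474 (without 3OFF replicate 1). Against group 12 it gave 1044 (without 3OFF replicate 1) to 1300 (without 3OFF replicate 2) higher and 743 (without 3OFF replicate 1) to 1237 (without 12 replicate 3) lower in 3OFF vs 12, and 133 (without 12 replicate 1) to 577 (without 7OFF replicate 3) higher and 187 (without 7OFF replicate 1) to 687 (without 7OFF replicate 3) lower in 7OFF vs 12. Besides 3OFF replicate 1, leaving out 12 replicate 1 moved the higher count, and 12 replicate 2 or 3OFF replicate 3 the lower count, of 3OFF vs 12 by over 1.5 times. Leaving out any library but 7OFF replicate 3 did so for the higher count of 7OFF vs 12, and replicates 1 and 2 of either group for the lower count. Of the genes changing the other way, the lower ones numbered 0 in each case at 1OFF and 1179 (without 12ON replicate 2) to 2014 (without 12 replicate 2) at 3OFF. At 2OFF they were 0 (without 12 replicate 1) to 904 (without 2OFF replicate 2) for higher and 0 (without 12 replicate 1) to 432 (without 2OFF replicate 2) for lower genes.

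Of the 200 list results, 107 lost their call with an estimated correlation, 29 with fry and 17 with a stricter filter, while 16 gained it with fry. Over these results, which cover 12ON vs 12 and the OFF groups vs 12ON, leaving out a library ended 26 calls and added 52, and a sex term added 4. In OFF vs 12 and 7OFF vs 1OFF it ended 54 calls. Of the 58 results of named genes, leaving out a library ended 12 calls over all fits, a test against a 1.5-fold change 5, the libraries with low Xist alone 5 and the mitochondrial share term 4. That term ended the calls of Mup7 and Mup17 in 12ON vs 12 (adjusted p = 0.0606 and 0.0581). It also ended those of Fabp6 in 3OFF and 7OFF vs 12ON (adjusted p = 0.0548 and 0.202). Low Xist alone ended those of Dbp, Ciart, Serpina3k and Fabp6 in 3OFF vs 12ON and of Esr1 in 7OFF vs 12ON. In 3OFF vs 12ON, Ciart no longer passed without any of the 3 12ON libraries or 3OFF replicate 3 (adjusted p from 0.0528 to 0.0712), and Fabp6 without 12ON replicate 2 or 3OFF replicate 2 or 3 (adjusted p from 0.107 to 0.11). In 7OFF vs 12ON, Fabp6 without 7OFF replicate 2 had an adjusted p = 0.0521. All alternatives planned were run.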

Other observations

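Some sex-biased liver genes differed between 7OFF and group 12. Against group 12, the male-biased genes Mup20 (5.32 ± 1.11), Cyp2d9 (2.88 ± 0.60), Hsd3b5 (6.93 ± 1.66) and Cyp4a12b (7.44 ± 1.91) rose, and Cyp3a41a, female-biased, fell (-3.29 ± 0.72). Of the 18 tested members of the list, 7 rose and 1 fell (9 and 1 adjusted over the list alone), with an adjusted p = 0.66 with an estimated correlation, and each of the 5 genes named lost its call without 7OFF replicate 1. High Xist was seen in 1 of the 3 libraries of each of these groups. The higher values rest largely on 7OFF replicate 1, which stood apart in Mup7, with 8853 CPM against 429 and 272 CPM in the others, and in Dbp, with 115 CPM against 2.62 and 3.50 CPM. Mup20 (5.92 without 12 replicate 1, 3.04 without 7OFF replicate 1), Cyp2d9 (1.63 without 7OFF replicate 1), Hsd3b5 (7.91 without 12 replicate 2, 2.10 without 7OFF replicate 1), Cyp4a12b (8.74 without 12 replicate 1, 6.80 without 12 replicate 3, 2.01 without 7OFF replicate 1, 8.03 without 7OFF replicate 3) and Cyp3a41a (-4.12 without 7OFF replicate 2) moved by over 1.5 times in fold. Mup20 no longer passed without 12 replicate 2 or 7OFF replicate 1 (adjusted p from 0.0507 to 0.0639), Cyp2d9 without 12 replicate 2 or 3 or 7OFF replicate 1 (adjusted p from 0.0502 to 0.0654), Hsd3b5 without 12 replicate 1, 2 or 3 or 7OFF replicate 1 (adjusted p from 0.0685 to 0.26), Cyp4a12b without 12 replicate 1, 2 or 3 or 7OFF replicate 1 (adjusted p from 0.0887 to 0.444) and Cyp3a41a without 7OFF replicate 1 (adjusted p = 0.0602).

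Some clock genes also differed between groups. Of the 15 tested members of the list, 9 rose and 0 fell in 3OFF vs 12ON (9 and 0 adjusted over the list alone), with an adjusted p = 0.25 with an estimated correlation. In 7OFF vs 12ON 5 rose and 0 fell (5 and 0 adjusted over the list alone), with an adjusted p = 0.359 with an estimated correlation. Npas2 and Cry1 were higher in 7OFF than in 12ON (3.87 ± 0.84 and 1.51 ± 0.31), and Per2 and Nr1d2 in 3OFF (2.19 ± 0.47 and 1.76 ± 0.44). The hour of sampling is not given in the sources used here, so a difference in hour and a difference in clock setting were not separated. The B cell gene Pax5 (2.20 ± 0.51) was higher in 7OFF than in 12ON, and was lower in 12ON than in group 12 (-2.71 ± 0.51).

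The test of the perivenous list and that of the other imprinted genes were planned, and the others here were chosen only after the result was seen. The labels date the OFF groups from injury, and the first days after carbon tetrachloride injury may explain part of their distance from group 12. The test set beforehand asked for a perivenous median under -1 in 1OFF and 2OFF vs 12, with acute phase and immediate early lists above group 12, or, against it, perivenous medians above -0.5. The perivenous medians were -1.392 and -1.245 and the immediate early medians 0.449 and 0.066, but the acute phase medians were -1.624 and -1.551, so neither condition was met. The 12ON group, sampled at 12 days, had a perivenous median of -1.435 and an acute phase median of -2.016 against group 12. A perivenous median under -1 therefore does not mark the first days of injury. With this test they cannot be told apart from another timing.

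Another reading is that the OFF groups are successive times after the end of MycER activation. The genes apart from group 12 numbered 5939, 6236, 3099 and 1027 in 1OFF, 2OFF, 3OFF and 7OFF, and those apart from 12ON 1, 0, 5754 and 7833. From 1OFF to 2OFF neither count went the way this reading needs, and over the later groups both did. Against 12ON the first step depended on the setting. DESeq2 called 125 higher and 389 lower than 12ON in 1OFF, and 269 and 650 in 2OFF. Against group 12 it called 3202 and 3134 in 1OFF and 3319 and 3238 in 2OFF, which is not a fall. Without 2OFF replicate 2, the 2OFF library nearest to 12ON, edgeR called 1505 genes against 12ON, and 2523 higher and 2384 lower than group 12. The reading may hold but stays open. H19 took 2.06%, 2.40%, 1.13% and 0.0276% of the counts in 1OFF, 2OFF, 3OFF and 7OFF, against 2.42% in 12ON. The labels do not state it, and it remains a hypothesis found and tested on the same libraries.

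Imprinted genes other than those named above went both ways in 12ON vs 12. Peg10, Phlda2, Plagl1, Igf2r, Impact and Airn rose, led by Airn (2.68 ± 0.55) and Phlda2 (2.07 ± 0.67), and Usp29 and Snrpn fell (-0.91 ± 0.26 and -0.66 ± 0.21). Camera in limma did not call them as a list of 23. Dlk1 lies with Meg3 and Rian, which had -0.92 ± 0.50 and -0.52 ± 0.45 and did not pass. Phlda2 (3.55 without 12 replicate 2, 1.38 without 12 replicate 3) moved by over 1.5 times in fold. Phlda2 no longer passed without 12 replicate 1 or 3 or 12ON replicate 3 (adjusted p from 0.0524 to 0.0839) and Snrpn without 12 replicate 1 or 12ON replicate 2 (adjusted p from 0.0585 to 0.0789).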
